A study of Mus musculus with 2 samples.

How the data were processed

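Total RNA was sequenced from megakaryocyte-erythroid progenitors (MEP) of the bone marrow of male C57BL/6J mice aged 5 to 6 weeks. These are sorted progenitor cells named for the erythroid and the megakaryocyte lineage. The series holds 1 group of 2 libraries, numbered in the labels as biological replicates 1 and 2. Each library has its own biosample entry, but both carry the same donor entry, so the sources do not say that separate mice gave the cells. Per the labels, each library was made from 100 ng of RNA depleted of ribosomal RNA with the ScriptSeq kit, with a size range of 200 to 1000 for replicate 1 and 215 to 1000 for replicate 2 (unit not stated).

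The deposited tables hold 1 value per gene or per transcript for each library. Per the file headers, they give an expected count (an estimated number of reads or fragments, not normalized), a TPM (a share of transcripts scaled over all rows of the table), an FPKM (fragments scaled by gene length and library size), a posterior mean TPM and the bounds of an interval of the TPM, whose level is not stated. The authors' tables use genome build mm10 and GENCODE annotation M4, per the text files deposited with them. The quantifying program is not given in the sources used here. No replicates were pooled.

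Gene symbols, gene classes and coordinates came from GENCODE M21, which uses the same assembly, after gene IDs were matched without their version. Of 43346 Ensembl gene rows, 42462 had a match and 884 did not. The tables also hold 97 spike-in rows, which had 0 counts in both libraries, and 26248 numbered rows, which were not used in the comparisons. Library totals were 39919884 expected counts for replicate 1 and 48043010 for replicate 2. A gene of 2 kb with the 3 counts taken as the floor for a count of 0 would have a TPM of 0.0164 in replicate 1 and 0.0112 in replicate 2. The libraries carry no molecular identifiers in these tables, so floors and counting intervals cover counting error only.

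With 1 group there is no comparison between conditions. The lists of lineage, state and pathway genes, the pairs of regulators and every test were fixed before the data were examined, except where stated. Of 383 list members, 1 was not found. Each list is described by the median of its members' TPM. For some lists the text adds the percentile of that median among 10000 random lists of protein-coding genes of the same size. These were drawn from nuclear protein-coding genes whether expressed or not. Of 21934 protein-coding genes, 8468 reached a TPM of 1 in both libraries, so a list of expressed genes can exceed them without being high among expressed genes. Lineage lists were compared by the difference of their medians of log2(mean TPM + 1), on which differences of low genes are understated. The test was a two-sided permutation of list membership with 100000 resamples, adjusted by Benjamini-Hochberg over the 13 comparisons. It runs across genes, which are not independent replicates, so its p-values describe the lists in these cells and not the spread between mice. The SD of the difference between the 2 libraries is given beside it.

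Regulator pairs were compared as log2 TPM ratios within each library. A ratio to a gene with 0 counts was computed against the floor of 3 counts, and a ratio to a gene with 1 to 3 counts has an exact binomial 95% interval. The shift of a list between replicates is the median of log2((TPM of replicate 2 + 1)/(TPM of replicate 1 + 1)) over members with a mean TPM of at least 1. It is given relative to the median of 10000 random lists matched on mean TPM in 20 bins, and it is called outside when it leaves their central 95%. No p-value was computed between the replicates. Genes differing between replicates are protein-coding genes with a mean TPM of at least 5 and at least 20 expected counts in all, whose ratio on that scale exceeds 2-fold. The common biological coefficient of variation was estimated with edgeR 4.0.16 from expected counts rounded to whole numbers, with TMM scaling, an intercept-only model and genes with at least 10 counts in both libraries. DESeq2 1.42.0 gave size factors for alternatives. Other steps used R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

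Named genes follow a rule set before the data were examined. It takes all members of the lists of surface markers, transcription factors, regulator pairs and isoform genes. Of every other list it takes the 4 members with the highest mean TPM. Of the lists of other cell types it takes any member over a mean TPM of 10. It also takes the 10 nuclear protein-coding genes with the highest mean TPM and the 10 genes with the largest fold in each direction between replicates. The text gives only part of the genes that the rule takes, chosen after their values were seen, and leaves out a pair of regulators and a surface marker. Genes named outside this rule are marked as chosen after their values were seen.

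Alternatives were another pseudocount, posterior mean TPM, FPKM, filters on low values, the mean of a list, each library alone, TMM and DESeq2 scaling and counts in place of TPM. Chosen after the data were seen were TPM rescaled to nuclear protein-coding genes without globins for 3 results, and list shifts over genes with at least 20 counts on TMM-scaled counts with a pseudocount of 0.1. Separate lists of mature neutrophil, NK cell and late erythroid genes were also written then, before the values of their members were seen. The statistics were tested on simulated data. Of 1000 random lists of 24 genes with no planted shift, 49 left the central 95% of matched lists, and all 100 lists with a planted log2 shift of 0.5 did. For the comparison of the erythroid with the megakaryocyte list, 4 of 100 pairs of random lists passed an unadjusted threshold of 0.05 with nothing planted, and 92 of 100 with a planted log2 difference of 2. For the comparison of the replicates, over 12253 genes, simulated coefficients of 0.1, 0.3 and 0.5 were estimated as 0.154, 0.317 and 0.510. Part of the simulated genes carried a planted 4-fold change, which adds to the estimate. These runs therefore do not show whether the method itself overstates a low coefficient.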

Results

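The data were gene and transcript levels of total RNA from mouse bone marrow megakaryocyte-erythroid progenitors (MEP), in 2 libraries of 1 group. Replicate 1 held 39919884 expected counts and replicate 2 held 48043010. At a TPM of at least 1 in both libraries, 8468 protein-coding genes, 161 long non-coding, 135 short non-coding and 319 pseudogenes were detected. At 10 expected counts in both these numbers were 10811, 477, 138 and 552, and with TPM rescaled to nuclear protein-coding genes without globins 9940, 344, 137 and 492. Among nuclear protein-coding genes the elongation factor Eef1a1 had the highest level, a TPM of 4069 ± 1262 (SD, n = 2), followed by Rpl36a, Rplp1, Rpl26, Rps3a1, Ptma, Hspa8, Npm1, Rpl32 and the histone gene Hist2h2aa1, at means from 2380 down to 1412. Genes of the replication machinery were also high. The 22 proliferation genes had a median TPM of 37.6, led by Pcna at 176 ± 29.7, Mcm6 at 118 ± 1.63 and Top2a at 114 ± 25.3 (SD, n = 2), above all 10000 random lists.

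The erythroid list stood far above the list of every other lineage examined. No reference cells of these lineages were measured. The gaps therefore also depend on which genes the lists hold, and they do not measure the share of each lineage in the RNA. The 26 erythroid genes had a median TPM of 21.7, and 24 of them reached a TPM of 1 in both libraries. The carbonic anhydrase genes Car1 (ENSMUSG00000027556.11, mm10 chromosome 3, 14766216 to 14808368) and Car2 (ENSMUSG00000027562.8, chromosome 3, 14886273 to 14900770) led with TPM of 715 ± 10.97 and 438 ± 15.3 (SD, n = 2). The water channel gene Aqp1 followed at 102 ± 10.7 and the transferrin receptor gene Tfrc at 70.8 ± 1.36. The 28 megakaryocyte genes had a median TPM of 0.78, with 10 at a TPM of 1 in both libraries.

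On the log2(mean TPM + 1) scale the erythroid median exceeded the megakaryocyte median by 3.67, with 3.18 in replicate 1 and 3.96 in replicate 2 (SD 0.56). The two-sided permutation test across genes gave an adjusted p of 4.3e-05. The erythroid list was also higher than the stem and multipotent list by 3.19, the granulocyte and monocyte list by 3.80 and the lymphoid list by 4.14. Against the mast cell, basophil and eosinophil list the difference was 4.34, against the macrophage and dendritic list 4.39, and against stroma and endothelium 4.50. Adjusted permutation p-values of these 6 comparisons lay at or below 0.00098, and each difference had the same sign in both libraries. With members at a mean TPM of at least 1 only, the macrophage and dendritic list kept 1 gene, Cd68. The stroma and endothelium list kept 1 gene, Pdgfrb. The differences of 3.53 and 3.58 no longer passed (adjusted permutation p = 0.22 for both), and a test against 1 gene has little power.

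**Figure D1:**
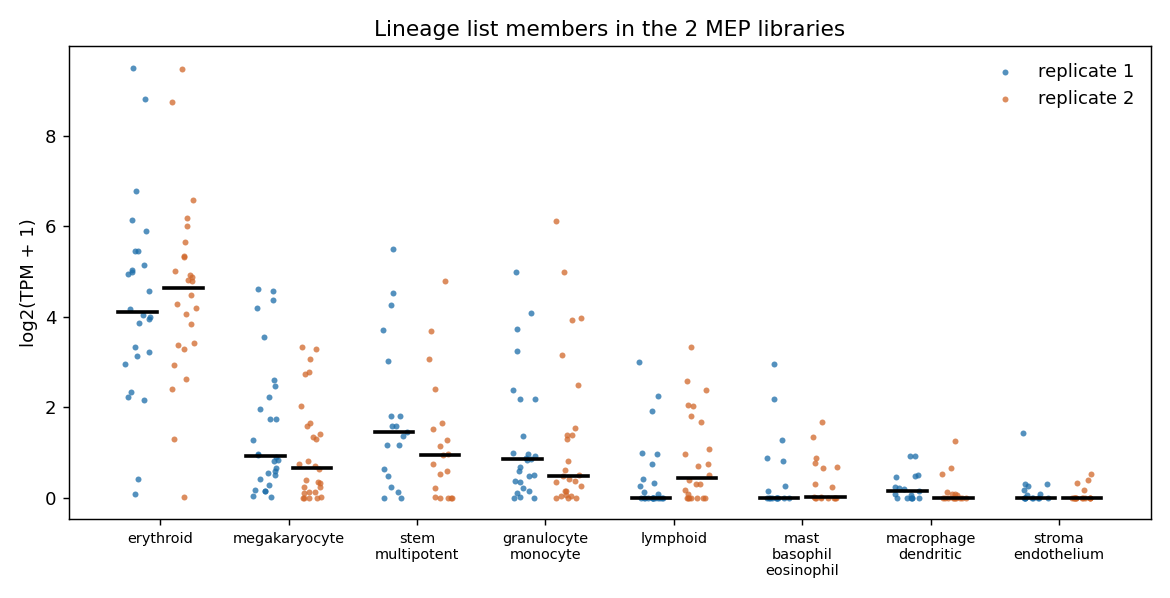
Points show log2(TPM + 1) of each member of 8 lineage lists in replicate 1 (blue) and replicate 2 (orange) of the MEP libraries, and black bars are medians. The erythroid medians lie above those of all other lists in both libraries, by 3.18 and 3.96 over the megakaryocyte list.

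Megakaryocyte genes had lower levels than erythroid genes, near those of stem and granulocyte genes. Their median lay at percentile 77.2 of random protein-coding lists, against 84.0 for the stem, 72.2 for the granulocyte and 57.5 for the lymphoid list. In TPM rescaled to nuclear protein-coding genes without globins the megakaryocyte median was 3.54 in replicate 1 and 2.87 in replicate 2. Pf4, which encodes platelet factor 4, had a TPM of 16.1 ± 10.4, the thrombin receptor gene F2r 15.9 ± 9.69, the integrin gene Itga2b 12.7 ± 9.86 and the pleckstrin gene Plek 11.7 ± 8.17 (SD, n = 2). The megakaryocyte median was above those of mast cell, basophil and eosinophil genes by 0.68, macrophage and dendritic genes by 0.72 and stroma and endothelium genes by 0.83 (two-sided permutation test, adjusted p = 0.043, 0.020 and 0.014). It was not separated from the stem and multipotent list, with a difference of -0.48 (adjusted permutation p = 0.46), the granulocyte and monocyte list, 0.14 (p = 0.71), or the lymphoid list, 0.47 (p = 0.19). Replicate 1 alone gave 0.93 against the lymphoid list (adjusted permutation p = 0.0031) and replicate 2 alone 0.22. None of the 3 differences that passed did so with members at a mean TPM of at least 1 only (adjusted permutation p = 0.58, 0.65 and 0.65). The differences themselves did not shrink, at 0.75, 1.00 and 1.05. The macrophage and stroma lists kept 1 gene each against 13 megakaryocyte genes, so permutation could not reach 0.05 for them.

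Genes of the other lineages had lower medians than erythroid genes, and these varied with the library. A TPM of 1 in both libraries was reached by 8 of 19 stem and multipotent genes, 6 of 26 granulocyte and monocyte genes, 3 of 24 lymphoid genes and 1 of 17 mast cell, basophil and eosinophil genes. The stem and multipotent list had a median TPM of 1.48 (1.74 in replicate 1 and 0.92 in replicate 2), led by Angpt1 at 27.96 ± 22.6, Mllt3 at 24.5 ± 3.25 and Cd34 at 9.86 ± 11.9 (SD, n = 2). The granulocyte and monocyte list had a median of 0.62 (0.81 and 0.405), led by the calprotectin genes S100a8 at 49.4 ± 26.5 and S100a9 at 23.3 ± 10.5, with the lysozyme gene Lyz2 at 13.3 ± 1.41. Of the lymphoid list, with a median of 0.285 (0 and 0.365), Nkg7 was highest at 6.02 ± 1.41. Cpa3, a mast cell protease gene, led the mast cell, basophil and eosinophil list at 4.17 ± 3.73, where the median was 0.115 (0 and 0.01). Macrophage and dendritic genes had a median of 0.080 (0.12 and 0), and no member of that list or of the stroma and endothelium list reached a TPM of 1 in both libraries.

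The list of hematopoietic transcription factor genes lay above random lists, which include genes not expressed here. In each pair of regulators or receptors below the first gene exceeded the second in both libraries. The 30 transcription factor genes had a median TPM of 8.86, above all 10000 random lists, and 27 reached a TPM of 1 in both libraries. Myb led at 129 ± 30.0, followed by Lmo2 at 94.5 ± 14.3, Ldb1 at 68.7 ± 15.1, Ikzf1 at 63.7 ± 0.54, Klf1 at 46.0 ± 4.24 and Gata1 at 33.6 ± 3.22 (SD, n = 2). Gata1 exceeded Gata2 by 2.10 ± 0.34 on the log2 TPM scale and the myeloid factor gene Spi1 by 4.62 ± 0.81. Klf1 exceeded the megakaryocytic factor gene Fli1 by 2.88 ± 1.14, and Kit exceeded Flt3 by 5.43 ± 0.45 (SD, n = 2).

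Gfi1b exceeded its paralog Gfi1 by 7.16 in replicate 1. In replicate 2, Gfi1 had 1 count and the ratio was 7886-fold, with a 95% counting interval from 1415 to 311524. The authors' TPM intervals there, 23.8 to 26.5 for Gfi1b and 0.0071 to 0.0695 for Gfi1, place the ratio below 7886-fold. Zfpm1 exceeded Cebpa by 4.76 on the log2 scale in replicate 1. In replicate 2, where Cebpa had 0 counts, Zfpm1 was at least 2339-fold higher against the floor. The counting interval and the floor cover counting error only, and the spread between these libraries was wider than that. In all 6 pairs the authors' intervals of the TPM of the pair lay apart in both libraries. No test of these ratios was run, since the lowest p of an exact two-sided sign test over 2 libraries is 0.5. Adding a pseudocount of 1 lowered the difference of Kit over Flt3 to 4.27.

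Of the surface marker genes, Kit and Ptprc were high, most markers of mature lineages were low or without counts, and Cd34 differed between the libraries. Kit had a TPM of 35.5 ± 10.7 and Ptprc, which encodes CD45, 25.4 ± 2.15 (SD, n = 2). Ly6a, Cd3e, Cd4 and Cd8a had 0 counts in both libraries. The Fc receptor gene Fcgr3 was at 0.51 ± 0.13, Itgam at 0.41 ± 0.18 and Il7r at 0.66 ± 0.64. Cd34 was at 18.3 in replicate 1 and 1.44 in replicate 2. Cd48 was at 8.50 ± 4.50, Eng at 3.73 ± 1.20 and Slamf1 at 1.47 ± 0.78. The list of 17 surface markers had a median of 0.515.

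Cytokine receptor genes had a median TPM of 1.11 over 24 genes, led by Ifngr1 at 54.2 ± 18.6, Kit, the IL-33 receptor gene Il1rl1 at 22.7 ± 2.43 and Epor at 8.88 ± 0.71 (SD, n = 2). The heme and iron list had a median of 14.2, with the ferritin genes Fth1 at 161 ± 9.40 and Ftl1 at 128 ± 4.36, and Cpox and Urod, enzymes of heme synthesis, at 38.6 ± 6.46 and 34.9 ± 0.41. Of 7 cyclin-dependent kinase inhibitor genes, with a median of 0.445 (0.13 in replicate 1 and 0.76 in replicate 2), Cdkn1b was highest at 10.3 ± 3.99. Cdkn2c followed at 7.81 ± 1.10. The immediate early genes Fos and Jun were at 66.8 ± 16.2 and 52.1 ± 22.8, in a list of 13 with a median of 11.995. Ribosomal protein genes had a median of 506. Among the long non-coding genes, Gas5 was at 696 ± 309 and Malat1 at 595 ± 250, and the median of the 15 found was 2.46.

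Short non-coding RNA dominated the TPM scale but not the counts. Short non-coding genes held 5.26% of counts in replicate 1 and 7.39% in replicate 2, but 68.0% and 74.4% of TPM. Gm22422 (ENSMUSG00000064994.1, mm10 chromosome 16, 56035753 to 56035887) alone held 21.1% and 14.9% of TPM with 0.162% and 0.119% of counts, at an effective length of 3.35 and 2.86 bases in the deposited tables. The RNA polymerase III transcript Rn7sk held 10.6% and 9.97% of TPM. Nuclear protein-coding genes held 87.0% and 84.9% of counts but 25.5% and 20.6% of TPM, so every TPM of a protein-coding gene is scaled by this share. Mitochondrial-encoded genes took 2.32% and 2.85% of counts, led by mt-Co1 with 482136 and 708273 counts. Gm22422, Rn7sk and mt-Co1 were named after their values were seen. Replication-dependent histone genes took 0.830% and 1.14% of counts, the 31 ribosomal protein genes 2.65% and 2.55%, and long non-coding genes 2.06% and 2.03%.

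Across 10602 genes at a TPM of at least 1 in either library, log2(TPM + 1) correlated between replicates with a Pearson r of 0.924 and a Spearman rho of 0.905. This correlation is across genes, which are not independent replicates. The common biological coefficient of variation was 0.37 over 12253 genes, and 0.81 without the filter on low counts. Of 9039 protein-coding genes with a mean TPM of at least 1, 91.8% lay within 2-fold. Their median log2 ratio of replicate 2 over replicate 1 was -0.27, and -0.0046 after TPM were rescaled to nuclear protein-coding genes without globins, a scaling chosen after the data were seen.

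The replicates differed in lineage genes, with erythroid genes higher and megakaryocyte and stem genes lower in replicate 2, relative to matched lists. Of 24 erythroid genes, 23 were above the median of matched lists and the list shift was 0.49. The heme and iron list shifted by 0.54, with 15 of 16 genes above, and 4 adult globin genes by 2.08. Megakaryocyte genes shifted by -0.96, with 2 of 13 above the matched median. Itga2b had a TPM of 19.6 in replicate 1 and 5.70 in replicate 2, and Pf4 23.5 and 8.71. Stem and multipotent genes shifted by -0.81, and by -1.22 over genes with at least 20 counts, with Angpt1 at 43.9 and 11.97 and Meis1 at 12.2 and 4.28, though Mllt3 was at 22.2 and 26.8.

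Markers of other cells differed too. The lymphoid list shifted by 1.07, and by 2.59 over 16 genes with at least 20 counts, with Gzma at 0 counts in replicate 1 and 792 in replicate 2. The granulocyte and monocyte list shifted by 0.82, with 9 of 11 genes above, and S100a8 was at 30.7 and 68.2 TPM. This call was lost over genes with at least 20 counts, where the shift was 0.47 and lay at percentile 96.3 of matched lists. At a mean TPM of at least 10 the shift was 1.24 over 3 genes. The mast cell, basophil and eosinophil list shifted by -0.77 over 4 genes, with 1 above the matched median. The shift was -1.18 to -1.40 with rescaled TPM, a pseudocount of 0.1 and TMM or DESeq2 scaling. Over 9 genes with at least 20 counts it was -1.61, but 4 of the 9 were above the matched median, so members were split in direction. The proliferation list shifted by 0.29 over 22 genes. All these lists lay outside the central 95% of 10000 matched lists. The shifts of transcription factors (-0.11), cytokine receptors (-0.12), cyclin-dependent kinase inhibitors (-0.24), ribosomal proteins (-0.039) and immediate early genes (-0.11) lay inside. Each replicate is 1 library, so these percentiles describe the pair and not MEP in general.

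**Figure D2:**
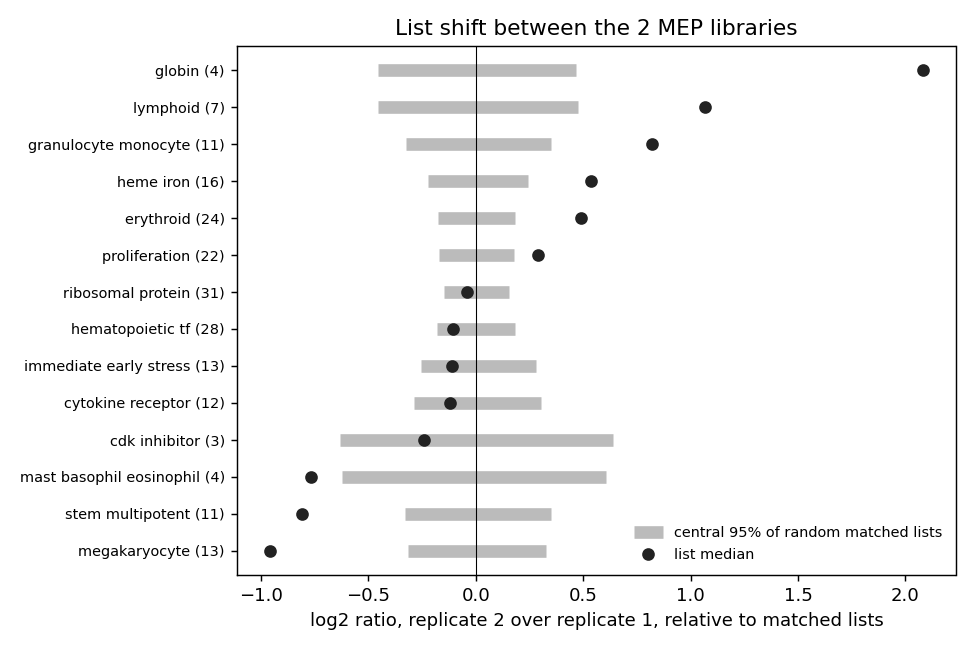
Points show the median log2 ratio of TPM + 1, replicate 2 over replicate 1, of each list relative to the median of 10000 random lists matched on mean TPM, and grey bars the central 95% of those lists, with the number of genes in parentheses. The globin list lies at 2.08 and the erythroid list at 0.49, while the stem list lies at -0.81 and the megakaryocyte list at -0.96.

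Single genes differed by more than 2-fold in both directions, in a balance set by the scaling. Of 5648 protein-coding genes tested by size alone, 53 were higher and 275 lower in replicate 2 on the TPM scale, while rescaled TPM gave 155 and 148, TMM-scaled counts 80 and 82, and DESeq2 size factors 81 and 79. Of the 53 and 275, 34 and 74 were also past 2-fold with TMM scaling. Cd34 was lower in replicate 2 with a log2 ratio of -2.98, as was Rgs1, a regulator of G protein signalling, at -2.73. Gimap4, a GTPase gene of lymphocytes, was higher at 2.98 and Ngp, a neutrophil granule gene, at 1.79. The beta globin gene Hbb-bs was higher at 2.60 and the alpha globin gene Hba-a1 at 1.84. Adult globin copies are nearly identical, so reads may be divided between them. All globin genes together took 0.00384% and 0.0142% of counts, a ratio of 3.69.

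The remaining genes of the rule include several whose reads can be shared. Gm10800, Atp5l, mt-Atp6, Hist2h3c2, mt-Co3 and mt-Nd3 were higher in replicate 2, at log2 ratios from 3.88 for Gm10800 to 1.86 for mt-Nd3. Gene mt-Co3, at 1.87, fell to -0.05 with the posterior mean TPM, and mt-Atp6, at 2.70, to 0.71. Lower in replicate 2 were mt-Nd4l (-4.56), Gm10226, Isoc2b, Axin1, Gm10260, Chmp6, Usp50 and Tcirg1 (-2.36). Axin1 had 2963 counts in replicate 1 and 3161 in replicate 2, so its log2 ratio of -2.56 in TPM is not present in its counts. Chmp6 and Tcirg1 were also within 2-fold with TMM-scaled counts. Mitochondrial genes have nuclear copies and some abut each other, so their values are uncertain.

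Most genes fixed for the comparison of isoforms had the same leading transcript in both libraries. This held for 16 of 21 genes with a TPM of at least 1 in both libraries. Klf1 and Epor, counted among the 16, have 1 transcript each, so they could not differ. Gata1-201 took 100% of its gene's TPM in both, Tal1-201 took 99.1% and 96.3%, and Lmo2-208 94.3% and 94.6%. Gata2 differed, with Gata2-201 (mm10 chromosome 6, 88198334 to 88207030) at 73.6% in replicate 1 and Gata2-202 (chromosome 6, 88193891 to 88207032) at 86.6% in replicate 2. For Kit, Kit-201 led in replicate 1 at 65.4% and Kit-204 in replicate 2 at 71.1%. The leading transcript also differed for Ldb1, Ank1 and Itga2b. These shares are estimates from short reads in 1 library each.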

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

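Of the tests in this part, the one of uneven reads on the erythroid and stem lists was chosen after the result was seen, as were the bootstrap interval and the TMM scale of the neutrophil list. Rows outside the comparisons held some signal. Numbered rows outside the gene annotation held 26 counts in replicate 1 and 1 in replicate 2, in 2 of 26248 rows, and gene rows whose ID has no match in the newer annotation held 119081 counts in replicate 1 and 139269 in replicate 2, which is 0.298% and 0.290% of counts. Apart from the numbered rows in replicate 2, these totals stand above the 3 counts taken as the floor.

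Erythroid genes were higher and stem genes lower in replicate 2, by a difference of 1.26 between the medians of their log2 ratios. Uneven reads of single genes, independent of each other, are argued against as the whole cause. Relative to matched lists the difference was 6.77 SD of random pairs. With all 14 lists replaced by random matched lists, the largest of 91 pairs reached it in 1 of 10000 draws. A trend with transcript length or GC content is also argued against as the whole cause, since a cubic fit on both took 6.71% of the variance of the ratios and left the difference at 1.41. With 1 group in the design no biological explanation was tested, and a different mix of stages in the sorted cells may remain, as may RNA handling that acts on these genes together.

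The calprotectin genes S100a8 and S100a9 and the granule gene Ngp were higher in replicate 2. The primary granule genes Mpo, Ctsg, Prtn3 and Elane of the same list were lower there. RNA or cells of mature neutrophils in replicate 2 may contribute to the rise, and whether the sort removed such cells cannot be told here. A separate list of 21 mature neutrophil genes does not decide it: its 7 members with a mean TPM of at least 1 had a median log2 ratio of -0.17, with a bootstrap 95% interval from -0.90 to 1.17, where matched lists ended at 0.26. On TMM-scaled counts the median over 16 members was 0.41, with an interval from -0.19 to 1.75 and at percentile 85.8 of matched lists, and 10 of 16 were higher in replicate 2, under the binomial limit of 11, so uneven reads of single genes could give such a count. Mmp8 and Ifitm6 had 0 counts in replicate 1 and 216 and 180 in replicate 2, while Retnlg had 26 and 1. Mmp8, Ifitm6 and Retnlg were named after their values were seen.

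Many genes had all their counts in 1 library. Of 11911 protein-coding genes with at least 20 counts in all, 857 had 0 in the other library, where a binomial split of the reads gives 0.00031. For totals of 5 to 20 counts the mean squared deviation from that split was 11.96 times the binomial variance, and 89.2% of these genes had 0 counts in 1 library. Few genes had few counts: 252 had 1 to 4 in all and 462 had 5 to 19. Within replicate 1 alone 219 had 1 to 4, 551 had 5 to 19 and 11209 had at least 20, and within replicate 2 alone 240, 316 and 11205. A difference between the cell pools does not bear on scarcity within 1 library, for which no expected number was computed. The mean ratio rose through every bin of totals to 90.7 at 1000 to 10000 counts, while the median ratio was 11.6 in the lowest bin and between 25.3 and 38.9 in the others. Several reads from each captured molecule and differences between the cell pools cannot be told apart here, since the ratio sets the spread between 2 single samples against counting noise alone and small totals cap it.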

How the results depend on the processing

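Chosen after the data were seen were rescaled TPM for genes detected, list shifts and genes that differ, and the setting with at least 20 counts. Of 104 alternatives of the list comparisons, 96 kept direction and side of the threshold. The erythroid over megakaryocyte difference did so in all. With members at a mean TPM of at least 1 only, erythroid over macrophage and stroma genes fell to 3.53 and 3.58, megakaryocyte over mast, macrophage and stroma genes no longer passed at 0.75, 1.00 and 1.05, and megakaryocyte over granulocyte genes turned to -0.50 (adjusted permutation p from 0.22 to 0.81). This filter leaves fewer genes, with 1 macrophage and 1 stroma gene, so tests against those lists have little power. With list means megakaryocyte over granulocyte genes was -0.015. Megakaryocyte over lymphoid genes ranged from 0.22 to 0.93 with 1 library left out and passed without replicate 2. A pseudocount of 1 gave 4.27 for Kit over Flt3. Every list shift kept its call under all settings except the granulocyte and monocyte list, at 0.47 over genes with at least 20 counts; at a mean TPM of at least 10 the stem, lymphoid, mast and kinase inhibitor lists gave no value. The correlation between replicates was 0.973 with all genes, 0.856 with a pseudocount of 0.1, 0.951 with TMM-scaled counts and 0.940 with posterior mean TPM. The coefficient of variation was 0.81 with no filter and 0.34 with protein-coding genes only. Genes over 2-fold higher and lower numbered 80 and 82 with TMM, 81 and 79 with DESeq2 size factors, 28 and 154 at a mean TPM of at least 10, and 155 and 148 with rescaled TPM. The log2 ratio of mt-Co3 turned to -0.050 with posterior mean TPM. In shares of TPM, mitochondrial genes took 1.94%, ribosomal protein genes 1.82%, histone genes 1.30%, long non-coding genes 0.786%, short non-coding genes 71.2% and nuclear protein-coding genes 23.1%. Except for the filter, the cause was not tested. Depth limits genes near the floor, where 1 library can decide a ratio.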

Other observations

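Genes of NK cells were higher in replicate 2. The list of 11 NK cell genes was written after Gzma and Klrb1c of the fixed lymphoid list had been seen, and neither is in it. Its 6 members with a mean TPM of at least 1 were all higher in replicate 2, with a median log2 ratio of 1.84, above all 10000 matched lists. On TMM-scaled counts the median over 11 members with at least 20 counts was 3.68. Ncr1, an NK cell receptor gene, had 49 counts in replicate 1 and 1102 in replicate 2, Klrk1 18 and 991, Il2rb 36 and 835, and Klra8 0 and 617. Gzmb was the exception among 11 members with at least 20 counts, at 52 and 12. Genes of T cells in the fixed list did not share this level, with Cd3e, Cd3d, Cd4 and Cd8a at 0 counts in both libraries and Cd3g at 12 and 89. Genes with 0 counts in both libraries cannot show a shift. Of 16 genes of the fixed lymphoid list with at least 20 counts, 13 were above the matched median in replicate 2. That list also holds B cell and progenitor genes, so the rise was not shown to be limited to NK cell genes. The genes in this part were named after their values were seen.

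Genes of the granulocyte and monocyte list differed in both directions. The genes named here were chosen after their values were seen and no test of granule types was run. The primary granule genes Mpo, Ctsg, Prtn3 and Elane had 1623, 303, 74 and 25 counts in replicate 1 and 502, 35, 10 and 5 in replicate 2. The later granule genes Ngp, Ltf and Camp had 305, 196 and 121 counts in replicate 1 and 1861, 1582 and 396 in replicate 2. Slc4a1, the anion exchanger of red cells, was at a TPM of 0.070 and 1.47, and Alas2, the erythroid enzyme that starts heme synthesis, at 0.060 and 0.98. The authors' intervals for Slc4a1, 0.115 to 1.30 and 1.53 to 2.87, lie apart but do not hold these values, so the size of its ratio is uncertain. Tmod1, another low gene of the erythroid list, went the other way, at 0.34 and 0.01. A separate list of 8 late erythroid genes had a median log2 ratio of 0.17 over 5 members, at percentile 93.0 of matched lists, and 0.61 over 7 members on TMM-scaled counts, at percentile 98.2.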
